A study of Mus musculus with 6 samples.

How the data were processed

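Poly(A) RNA of 6 libraries from the mouse cholangiocarcinoma line LD-1 was sequenced as read pairs on an Illumina NovaSeq, per the labels' protocols, with 3 libraries stimulated with HGF and 3 controls. A table of the whole series with 28212 genes holds a count column and an FPKM column for each library, per the file headers. The authors' counts are whole numbers per gene and were used as deposited. The authors' FPKM (fragments per length of transcript and library size) are deposited values normalised for library size and gene length. The submitters' processing notes name Bowtie 0.12.2, HISAT2 2.0, StringTie 1.3.0 and build mm8. The role of each tool, the annotation release and whether counting used strand are not given in the sources used here, so overlapping genes on opposite strands could share counts. Of the gene identifiers, 28133 are in GENCODE M21 (GRCm38) and 25351 of these have the same chromosome, start and end there, so coordinates are printed as the table gives them, and for most genes they are those of GRCm38. The protocol text of the labels also speaks of adipose material, and the meaning of that is unknown here.

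Groups came from the sample titles, and each table column was matched to its sample by name. All 12 per-sample columns were used. Before the data were examined the design, the alternatives and 40 gene lists were fixed. The design had assumed FPKM and named the count test as the main one in case the table held counts, which it did. Counts were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over 17322 genes and a threshold of 0.05. TMM factors were 0.963 to 0.968 for the HGF libraries and 1.03 to 1.04 for the controls. Ratios of FPKM with HGF over control lack this scaling and are lower than the fitted ratios. In FPKM, rises with HGF therefore look smaller and falls look larger than the fitted folds. The standard error of a log2 fold change was its size divided by the square root of the F statistic. The common biological coefficient of variation was 0.155.

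Gene lists with at least 5 measured members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01, and again with an estimated correlation and with fry, each adjusted over the lists. KEGG and Gene Ontology terms of the deposited table with 10 to 200 tested genes were treated alike, adjusted within each annotation. KEGG terms of 6 genes and Gene Ontology terms of 2087 genes were not used here, so terms may lack members. Single genes were called over all tested genes and again adjusted over each list alone. Genes named in the text followed a fixed rule. It took Met and Hgf, then the 10 higher and 10 lower genes with the largest change among those past the threshold with a mean FPKM of at least 5 in the higher group, groups that did not overlap and a symbol that is not a predicted or unnamed locus. It also took up to 4 members per list with the smallest p among those past the threshold, or up to 2 with the highest mean FPKM where none passed, and some of these were left out of the text for length. Some genes and 1 list are not reported here, though all counts include them. Other genes are said to have been chosen after their values were seen.

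Libraries of the same group had Pearson correlations of log2 CPM of 0.971 to 0.987, and their counts differed by more than sampling noise (chi-square per degree of freedom 2.84 to 7.09 in read pairs), so none was treated as a duplicate. Since a read pair appears to weigh 4 counts, the floor for a group at 0 was set at 3 read pairs, or 12 counts, over the group.

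Alternatives were DESeq2 1.42.0, no low-count filter, median-of-ratios scaling, a block for the replicate number, each library left out in turn, and limma on log2(FPKM + 1), where genes needed an FPKM of at least 1 in 3 libraries, with other pseudocounts, filters, scalings and variance models. With limma on FPKM a fold change is on the log2(FPKM + pseudocount) scale and understates the change of low genes. Counts divided by 4, a per-library correction for GC content and the removal of liver, muscle and macrophage genes were added after seeing the data. Further lists of liver, skeletal muscle, macrophage, hepatocyte transcription factor and mitotic genes were chosen after seeing the data.

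The count test was tested on simulated data, in 5 simulations of HGF against control with 200 changed genes each, drawn from the real means and library sizes, of which 16771 to 16837 genes passed the filter. It recovered 54.5% of genes changed 1.5-fold, 65.2% of those changed 2-fold and 81.5% of those changed 4-fold, of 325 each. Unchanged genes made up 8.13% of all calls (68 genes), above the nominal 5%. A list shifted 1.41-fold was called in 5 of 5 simulations, and 1 other list was called over all of them. Each gene was drawn independently, so the simulations hold no correlation between genes and cannot test the preset correlation of camera. They also changed far fewer genes than the 38.5% called in the data, so recovery and the share of false calls may differ there.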

Results

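RNA sequencing measured gene expression in LD-1, a mouse line of cholangiocarcinoma, the cancer of bile duct cells. The cells were stimulated with hepatocyte growth factor (HGF), the ligand of the receptor tyrosine kinase Met, or left as controls, with 3 libraries in each group. The stated purpose was to assess how HGF alters expression in these cells. The labels name the material both as this cell line and as cholangiocarcinoma tissue, and give neither the dose of HGF nor the time of exposure. Total counts per library ranged from 57073866 (Control 3) to 66302502 (Control 1). In the table a count of 4 was more frequent than 3 or 5 (a mean of 1108.5 genes per library against 527.33 and 306), so a read pair appears to weigh 4 counts and the number of independent molecules is lower than the totals. Counts of 1 and 2 were also common (means of 814.67 and 701.17 genes), which a weight of 4 alone would not give, so this weight is rough. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. Below, log2 fold changes are HGF minus control ± SE, and FPKM values are means ± SD over 3 libraries per group.

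HGF was followed by changes of similar number in both directions, with the larger ones on the higher side. Of 17322 genes tested, 6665 passed adjusted p 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 3316 higher and 3349 lower with HGF. Of these, 1000 changed at least 2-fold, 585 higher and 415 lower, and 383 of the 1000 had a mean FPKM of at least 1 in the higher group (256 higher and 127 lower). Most calls were small, since 4029 (60.45%) had an absolute log2 fold change under 0.5. The HGF and control libraries did not overlap in 8905 tested genes (51.4%, where chance gives 10%). With the deposited FPKM scaling and limma on log2(FPKM + 1), 32.7% of calls were higher in place of 49.8%, and 133 calls reached 2-fold.

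Among genes that met the naming rule, with a mean FPKM of at least 5 in the higher group, those that rose most include secreted proteases, a protease inhibitor, matrix proteins and a cytokine, and some hepatocyte markers at lower levels rose more. Il24, a cytokine of the interleukin-10 family, rose 13.9-fold (log2 3.80 ± 0.21, adjusted p = 5.58e-06), from an FPKM of 0.388 ± 0.114 to 5.16 ± 0.145. Mmp3 and Mmp10, the stromelysins, rose by log2 3.77 ± 0.35 and 3.53 ± 0.10 (adjusted p = 6.97e-05 and 2.71e-07), Mmp10 from an FPKM of 1.70 ± 0.122 to 18.3 ± 1.82. Mmp13, a collagenase, rose by 2.66 ± 0.11 (adjusted p = 1.60e-06). These 3 genes lie in a cluster on chromosome 9, Mmp13 (ENSMUSG00000050578) at 7272514 to 7283331, Mmp3 (ENSMUSG00000043613) at 7445822 to 7455975 and Mmp10 (ENSMUSG00000047562) at 7502352 to 7510240. Coordinates are as deposited: the submitters' processing notes name build mm8, but 90.1% of the gene identifiers shared with the GENCODE M21 annotation of GRCm38 carry that annotation's coordinates exactly. Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706), a fibrillar collagen, rose 5.97-fold from an FPKM of 5.42 ± 0.444 to 30.3 ± 1.49 (adjusted p = 1.36e-07). Tnc, a matrix glycoprotein of the tenascin family, rose by 2.48 ± 0.13, and Serpinb2, an inhibitor of plasminogen activators, by 2.67 ± 0.07. Krt13, a keratin of stratified epithelia, rose by 3.43 ± 0.16, the long noncoding RNA Wincr1 by 2.91 ± 0.23, and Havcr2, which encodes the immune checkpoint receptor TIM-3, by 2.45 ± 0.10.

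Among genes that met the same rule, those that fell most changed less. Hes1 (ENSMUSG00000022528, chromosome 16, 30064384 to 30067796), a transcriptional repressor downstream of Notch, fell by 1.45 on the log2 scale (SE 0.08, adjusted p = 5.25e-06), from an FPKM of 42.0 ± 3.55 to 14.4 ± 0.841. Ccn1 (ENSMUSG00000028195, chromosome 3, 145646976 to 145649981), a matricellular protein gene used as a readout of YAP and TEAD, fell from an FPKM of 209 ± 3.17 to 89.5 ± 2.94 (log2 -1.12 ± 0.04, adjusted p = 4.89e-07). Amotl2, an angiomotin family gene that YAP also drives, fell by 1.11 (SE 0.05), and the stress-inducible Gadd45b by 1.29 (SE 0.08). Trnp1, Rogdi, P2rx5, Sgcb and Habp4 had log2 fold changes of -1.35 ± 0.19, -1.34 ± 0.14, -1.22 ± 0.10, -1.18 ± 0.07 and -1.15 ± 0.08. Pgam2, the muscle form of phosphoglycerate mutase, had the largest value of these at -2.36 ± 0.32 (adjusted p = 5.87e-04), and its control FPKM was uneven (5.95, 6.92 and 14.1). Without Control 3 it was -1.86 (adjusted p = 1.56e-04), and that library also held the highest share of skeletal muscle transcripts, 0.0114% of its counts against 0.00174% and 0.00195% in the other controls.

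**Figure D1:**
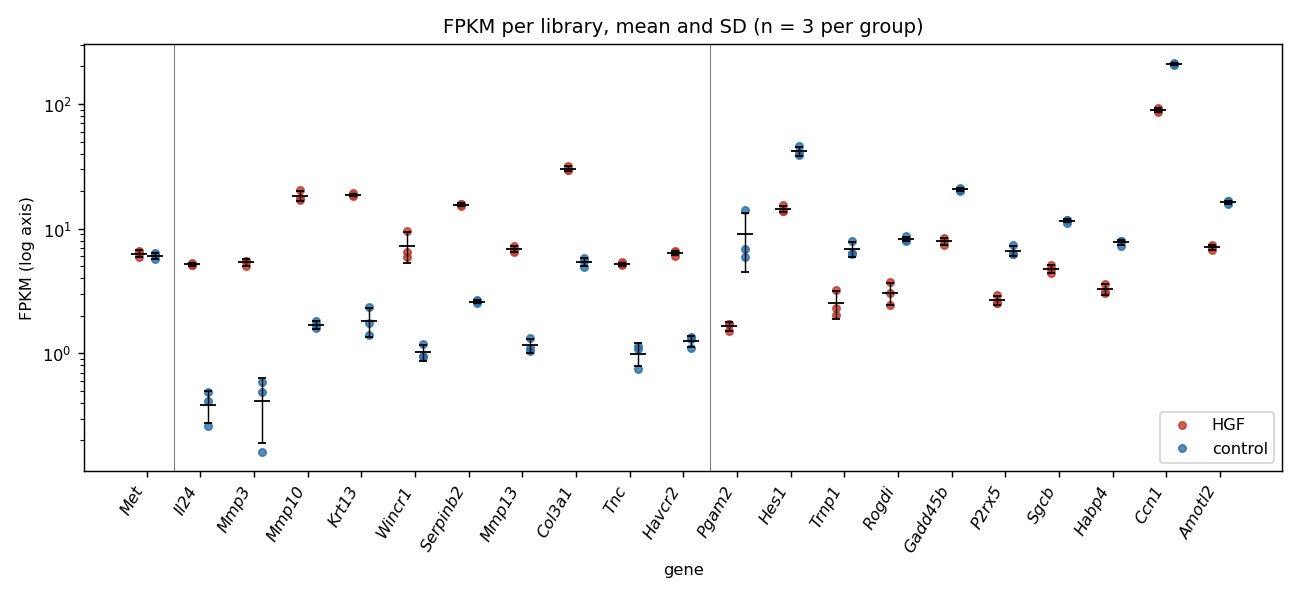
FPKM of Met and of the 10 genes with the largest rise and the 10 with the largest fall among those that met the naming rule (mean FPKM of at least 5 in the higher group), on a logarithmic axis, with each library as a point (red HGF, blue control) and the mean and SD of 3 libraries in black. Met lies at 6.32 with HGF and 6.08 in controls, whereas the HGF points of Mmp10 average 18.3 against 1.70 and those of Ccn1 89.5 against 209.

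The HGF receptor and its ligand gave no call. Met (ENSMUSG00000009376, chromosome 6, 17463800 to 17573980) had an FPKM of 6.32 ± 0.363 with HGF and 6.08 ± 0.312 in controls, a log2 fold change of 0.15 ± 0.06 that missed the threshold (adjusted p = 0.0819). Hgf itself was under the expression filter, with counts of 4, 7 and 12 in the HGF libraries and 0, 1 and 8 in the controls. Of 20 measured genes of the receptor, its activators and its adaptors, 3 rose and 2 fell (4 adjusted over the list alone, camera adjusted p = 0.230). Cd44, a co-receptor of Met, rose by 0.80 ± 0.04, Spint1, an inhibitor of the HGF activator, by 1.22 ± 0.10, and Stat3 by 0.33 ± 0.06. The adjusted p of Met passed the threshold at 0.0332 without HGF 1, 0.04997 with quantile-normalised FPKM and 0.0233 with a GC correction, and ranged up to 0.588 over the alternatives.

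Most genes listed as output of the ERK kinases rose. Of 25 measured ERK output genes, 18 rose and 0 fell (18 adjusted over the list alone), with a median log2 fold change of 0.48 (camera adjusted p = 4.60e-10, and adjusted p = 0.0572 with an estimated correlation). Areg, the EGF receptor ligand amphiregulin, rose from an FPKM of 15.4 ± 0.369 to 55.8 ± 2.03 (log2 1.96 ± 0.05, adjusted p = 2.64e-07). Ccnd1, which encodes cyclin D1, rose by 0.81 ± 0.04, the transcription factor gene Etv4 by 0.72 ± 0.04 and the chromatin protein gene Hmga2 by 1.03 ± 0.07. Of 20 EGF family ligands and growth factor receptors, 9 rose and 2 fell (11 adjusted over the list alone, median 0.31, camera adjusted p = 0.00146, and adjusted p = 0.394 with an estimated correlation). The ligand gene Btc rose by 1.72 ± 0.09 and Errfi1, a feedback inhibitor of the EGF receptor, by 0.94 ± 0.05. Immediate-early genes went both ways, 11 higher and 6 lower of 25 (21 adjusted over the list alone, camera adjusted p = 0.332): Jun rose by 0.88 ± 0.06 and Maff by 0.81 ± 0.05, whereas Fos fell from an FPKM of 22.1 ± 0.419 to 10.5 ± 0.192.

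Most of the listed proteases that act at the cell surface and their inhibitors rose. Of 25 measured, 18 rose and 3 fell (21 adjusted over the list alone), with a median log2 fold change of 0.79 (camera adjusted p = 6.64e-10, and adjusted p = 0.138 with an estimated correlation). Members that rose include inhibitors as well as proteases, among them Serpine2, a serine protease inhibitor gene, by 1.51 ± 0.06. Of 24 mesenchymal genes, 14 rose and 0 fell (15 adjusted over the list alone, median 0.63, camera adjusted p = 3.85e-08, and adjusted p = 0.0572 with an estimated correlation). S100a4, a calcium-binding protein gene linked to motility, rose from an FPKM of 66.3 ± 3.37 to 330 ± 16.7, Fn1, which encodes fibronectin, from 44.1 ± 2.70 to 118 ± 5.20, and the intermediate filament gene Vim from 445 ± 3.27 to 629 ± 10.5. Fibroblast markers rose in 9 of 11 and fell in 0 (9 adjusted over the list alone, median 0.89, camera adjusted p = 7.02e-06, and adjusted p = 0.0572 with an estimated correlation), among them Col1a1 by 1.57 ± 0.10 and Pdpn by 0.55 ± 0.05. Integrins and laminins split into 11 higher and 4 lower of 22 (16 adjusted over the list alone, median 0.32, camera adjusted p = 0.00799, and adjusted p = 0.487 with an estimated correlation). The integrin subunit gene Itga6 rose by 0.86 ± 0.05, and the laminin chain gene Lamb2 fell by 0.62 (SE 0.04).

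Some cholangiocyte markers rose and none fell, while junction, WNT and YAP-TEAD genes had members in both directions. Of 21 cholangiocyte markers, 8 rose and 0 fell (9 adjusted over the list alone, median 0.48, camera adjusted p = 1.55e-04, and adjusted p = 0.145 with an estimated correlation). Krt19, a keratin of bile duct cells, rose from an FPKM of 63.5 ± 2.30 to 165 ± 6.13, and Spp1, which encodes osteopontin, from 115 ± 12.7 to 310 ± 30.1. Krt8 and Krt18, the keratins of simple epithelia, rose by 0.69 ± 0.04 and 0.88 ± 0.03. Epithelial junction genes gave 6 higher and 2 lower of 25 (8 adjusted over the list alone, camera adjusted p = 0.176), with Grhl2 higher by 0.85 ± 0.09 and F11r lower (log2 -0.51 ± 0.04). WNT targets and stem cell genes gave 10 higher and 5 lower of 23 (16 adjusted over the list alone, median 0.63, camera adjusted p = 0.0158, and adjusted p = 0.277 with an estimated correlation), a call lost with an FPKM minimum of 5 (median 0.35, adjusted p = 0.216), and the Notch ligand gene Jag1 rose by 0.94 ± 0.08 while Hes1 fell. YAP-TEAD targets went both ways, 7 higher and 8 lower of 24 (16 adjusted over the list alone, camera adjusted p = 0.492): Ccn2 fell by 1.01 (SE 0.07) like Ccn1, and Wwc1, a scaffold of the Hippo pathway, rose by 0.69 ± 0.05. TGF-beta targets gave 7 higher and 4 lower of 24 (11 adjusted over the list alone, camera adjusted p = 0.690, direction up), with a median of -0.07 and a mean of 0.25, and the inhibitor of differentiation Id1 fell by 0.33 (SE 0.04).

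Many NF-kB targets, chemokines and cytokines and many angiogenic factors rose. Of 31 genes in the first list, 20 rose and 1 fell (23 adjusted over the list alone, median 0.56, camera adjusted p = 1.21e-07, and adjusted p = 0.0572 with an estimated correlation). Ptgs2, which encodes cyclooxygenase-2, rose from an FPKM of 6.70 ± 0.195 to 19.3 ± 1.94, and the chemokine genes Ccl7 and Cxcl1 rose by 1.91 ± 0.11 and 0.76 ± 0.07. Of 24 angiogenic factors, 15 rose and 0 fell (16 adjusted over the list alone, median 0.48, camera adjusted p = 1.07e-06, and adjusted p = 0.0572 with an estimated correlation). Angpt2, a ligand of the endothelial receptor Tie2, rose by 1.92 ± 0.09, and Vegfd, a lymphatic growth factor gene, by 1.11 ± 0.07. Thbs2, which rose by 1.44 ± 0.08, is an inhibitor of vessel growth. Immune checkpoint ligands and modulators rose in 9 of 17 and fell in 0 (10 adjusted over the list alone, median 0.23, camera adjusted p = 0.00578, and adjusted p = 0.138 with an estimated correlation), with the arginine-degrading enzyme gene Arg1 at 2.40 ± 0.19 and Cd276 at 0.43 ± 0.05. Hepatocyte markers rose in the same HGF libraries, and whether liver RNA adds to the value of Arg1 was not tested. With limma on log2(FPKM + 1) the checkpoint list missed the threshold (adjusted p = 0.0595), as it did in every limma fit except those with no filter or TPM. Its adjusted p was 0.175 with quantile-normalised FPKM and 0.184 with an FPKM minimum of 5.

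Class II antigen presentation genes were among those that fell. H2-Ab1 and H2-Eb1, chains of the class II molecules, had log2 fold changes of -2.30 ± 0.35 and -2.82 ± 0.45 at low levels (control FPKM 0.739 ± 0.274 and 0.915 ± 0.219), and Cd74, their invariant chain, fell from an FPKM of 18.6 ± 0.829 to 9.54 ± 0.615 (adjusted p = 5.65e-05). Class II genes are also expressed by macrophages, and Control 3 held more of some macrophage transcripts (Adgre1, chosen after its values were seen, 963 counts against 12 and 19). Without that library H2-Ab1 was at -1.97 (adjusted p = 0.00281) and H2-Eb1 at -2.87 (adjusted p = 0.00318). The class I gene H2-M3 rose by 0.52 ± 0.07. Over the antigen presentation list 5 genes rose and 9 fell of 24 (17 adjusted over the list alone, camera adjusted p = 0.259). Genes of the H2 family share sequence, and reads could be split between them. Interferon response genes gave 12 higher and 5 lower of 30 (19 adjusted over the list alone, camera adjusted p = 0.159), with Oasl1 higher by 1.02 ± 0.06 and Gbp2 lower (log2 -0.52 ± 0.05).

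Metabolic and growth genes rose in several groups. Of 27 glycolysis and hypoxia genes, 23 rose and 0 fell (23 adjusted over the list alone, median 0.46, camera adjusted p = 2.31e-11, and adjusted p = 0.175 with an estimated correlation), with Hk2, the inducible hexokinase, at 0.92 ± 0.05 and the abundant enolase gene Eno1 at an FPKM of 760 ± 31.6 against 483 ± 9.86. Cholesterol synthesis and uptake genes rose in 22 of 25 and fell in 2 (24 adjusted over the list alone, median 0.55, camera adjusted p = 9.59e-10, and adjusted p = 0.145 with an estimated correlation). Fdps, which encodes farnesyl diphosphate synthase, rose by 0.76 ± 0.04, and Fdft1, which encodes squalene synthase, by 0.74 ± 0.05. Fatty acid synthesis genes gave 11 higher and 5 lower of 22 (17 adjusted over the list alone, median 0.24, camera adjusted p = 0.0254, and adjusted p = 0.277 with an estimated correlation), with Fasn at 0.80 ± 0.07, but this call missed the threshold with quantile-normalised FPKM (adjusted p = 0.0932) and with a GC correction (adjusted p = 0.0503). Genes of MYC output and ribosome biogenesis rose in 23 of 28 and fell in 0 (24 adjusted over the list alone, median 0.39, camera adjusted p = 6.64e-10, and adjusted p = 0.0572 with an estimated correlation). The spermidine synthase gene Srm led at 0.87 ± 0.04 and Fbl, a nucleolar methyltransferase, followed at 0.65 ± 0.04. Ribosomal protein genes rose in 30 of 34 and fell in 0 (30 adjusted over the list alone), by a small median of 0.27 (camera adjusted p = 3.18e-12, and adjusted p = 0.212 with an estimated correlation), for example Rpl3 at 0.49 ± 0.04. Amino acid and ATF4 response genes gave 10 higher and 4 lower of 26 (15 adjusted over the list alone, camera adjusted p = 0.135), with the serine synthesis gene Phgdh at 0.47 ± 0.05.

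Chaperones, antioxidant genes and the respiratory chain showed mixed members. ER chaperones rose in 12 of 22 and fell in 3 (15 adjusted over the list alone, median 0.17, camera adjusted p = 0.00592, and adjusted p = 0.196 with an estimated correlation), with the disulfide isomerase gene Pdia4 at 0.55 ± 0.04. With quantile-normalised FPKM the median of the ER list was -0.02 (adjusted p = 0.449), and with an FPKM minimum of 5 it missed the threshold (adjusted p = 0.0584). NRF2 antioxidant genes gave 13 higher and 3 lower of 22 (16 adjusted over the list alone, median 0.32, camera adjusted p = 3.55e-04, and adjusted p = 0.0765 with an estimated correlation), with Nqo1 at 0.52 ± 0.05 and Gstm2 lower (log2 -0.47 ± 0.05). The NRF2 call missed the threshold with quantile-normalised FPKM (adjusted p = 0.121) and with an FPKM minimum of 5 (adjusted p = 0.0584). Heat shock genes gave 4 higher and 2 lower of 15 (6 adjusted over the list alone, camera adjusted p = 0.815). Nuclear genes of oxidative phosphorylation gave 8 higher and 4 lower of 32 (12 adjusted over the list alone), with a median of -0.02 and a camera direction of up (adjusted p = 0.970), and Ndufb10 fell by 0.35 (SE 0.05) while Sdhb rose by 0.23 ± 0.06, a call lost without HGF 2 or Control 2 (adjusted p = 0.0577 and 0.0541) and with limma on log2(FPKM + 1) (adjusted p = 0.0648). Protein-coding transcripts of the mitochondrial genome fell in 10 of 13 and rose in 1 (11 adjusted over the list alone, median -0.37, camera adjusted p = 6.11e-04, and adjusted p = 0.394 with an estimated correlation), with mt-Cytb at -0.63 ± 0.07. The share of counts from the mitochondrial genome was 2.17%, 2.29% and 2.44% in the HGF libraries and 2.61%, 2.82% and 2.78% in the controls. A GC correction chosen after seeing the data turned the direction of this list (median 0.11, adjusted p = 5.16e-04).

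Cell cycle genes moved apart. Of 30 genes of the G1/S transition and DNA replication, 14 rose and 2 fell (18 adjusted over the list alone, median 0.14, camera adjusted p = 0.00578, and adjusted p = 0.333 with an estimated correlation). Mcm3, a subunit of the replicative helicase, rose by 0.57 ± 0.05, and the thymidine kinase gene Tk1 by 0.46 ± 0.04. Of 30 genes of G2 and mitosis, 2 rose and 17 fell (19 adjusted over the list alone, median -0.17, camera adjusted p = 3.36e-04, and adjusted p = 0.357 with an estimated correlation). Cdc25c, a phosphatase that activates the mitotic kinase, fell by 0.53 (SE 0.06), Cenpf, a kinetochore gene, by 0.71 (SE 0.10), and Mad2l1, a spindle checkpoint gene, by 0.39 (SE 0.06). With limma on log2(FPKM + 1) the G1/S list missed the threshold (adjusted p = 0.0535). The same held in every other limma fit except that with median-of-ratios scaling. The median of the G1/S list was 0.0781 with quantile-normalised FPKM (adjusted p = 0.1002) and 0.0588 with an FPKM minimum of 5 (adjusted p = 0.1157). Among p53 targets 10 rose and 5 fell of 26 (16 adjusted over the list alone, camera adjusted p = 0.230), with Cdkn1a, which encodes the cell cycle inhibitor p21, at 0.69 ± 0.04 and the stress cytokine gene Gdf15 at 1.36 ± 0.08. Apoptosis regulators gave 5 higher and 8 lower of 27 (15 adjusted over the list alone, camera adjusted p = 0.971). Of 20 replication-dependent histone genes, 1 fell (H1f2, log2 -0.33 ± 0.04) and 0 rose (1 adjusted over the list alone, camera adjusted p = 0.690). How well poly(A) libraries capture these transcripts was not tested, so no conclusion on replication is drawn from them.

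**Figure D2:**
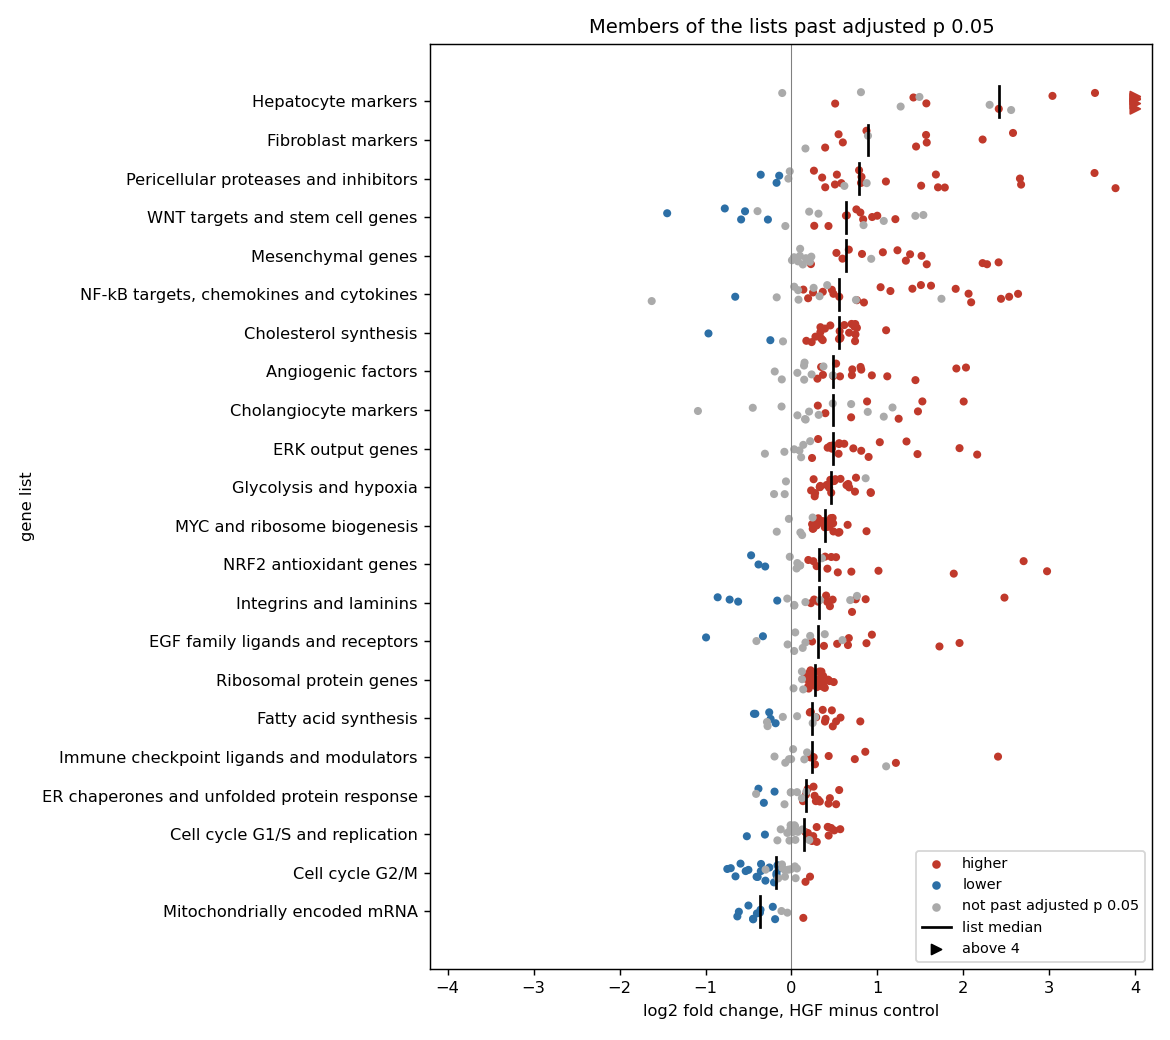
Log2 fold change (HGF minus control) of each member of 22 of the 23 gene lists past camera adjusted p 0.05, with a point per gene (red higher, blue lower, grey not past adjusted p 0.05), a black line at the list median and triangles for values above 4. The lists are ordered by median, from -0.37 for mitochondrial transcripts, which a GC correction turned to 0.11, to 2.41 for hepatocyte markers.

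Across the 40 lists, all fixed before the data were examined, 39 had enough measured genes for a test and 23 passed (21 up and 2 down). With an estimated correlation 0 of the 39 passed camera at adjusted p 0.05 (12 at an unadjusted p under 0.05), whereas 30 passed fry, which tests whether a list moves one way and does not compare it with other genes. With the preset correlation, the 9 splits of the libraries that mix the groups also gave 9 to 21 lists past the threshold.

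Some markers of other cell types were uneven between libraries. Hepatocyte markers rose in 11 of 17 and fell in 0 (12 adjusted over the list alone, camera adjusted p = 4.34e-06, and adjusted p = 0.266 with an estimated correlation), with a median log2 fold change of 2.41, or 2.31 with the 4 genes whose control counts lay under the floor of 12 counts over the group set at that floor. Alb, which encodes albumin, had counts of 485, 559 and 1071 with HGF and 0, 29 and 12 in controls, a 53.7-fold difference. Fgb, a fibrinogen chain gene, had 75, 115 and 139 with HGF and 0 in each control (at least 28.5-fold higher), Ahsg, a plasma glycoprotein gene of hepatocytes, 388 counts against 15, and Fga 362 against 4. The highest of these means, that of Alb, was an FPKM of 4.16 ± 1.83. The floor covers counting error only. Myeloid markers gave 3 higher and 1 lower of 15 (4 adjusted over the list alone), with a median of -0.62 and a camera direction of up (adjusted p = 0.510). The lysosomal gene Cd68 rose by 0.89 ± 0.06, Cd14 by 0.63 ± 0.10 and Ly6g by 2.30 ± 0.18, the last in a family of near-identical genes. C1qc, a complement gene of macrophages, had a log2 fold change of -4.57 ± 1.45 (adjusted p = 0.0348) that rested on Control 3, with counts of 21, 22 and 487 in the controls. Without that library its value was -1.35 (adjusted p = 0.376), and it also missed the threshold without HGF 1, HGF 2 or HGF 3 (adjusted p = 0.0665 to 0.106). The edgeR fit with the replicate number as a block gave C1qc -3.64 (adjusted p = 0.0592), and the call was also lost with no low-count filter (adjusted p = 0.0886). Without Control 3 the myeloid list had a median of 0.41 (adjusted p = 0.0155).

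Markers of the remaining cell types were few and mostly did not pass. Endothelial markers gave 1 higher (Eng, log2 0.62 ± 0.14) and 1 lower (Egfl7, -0.41 ± 0.07) of 10, with 2 adjusted over the list alone (camera adjusted p = 0.971). Adipocyte and erythroid markers gave 1 higher and 1 lower of 10, with 1 adjusted over the list alone (camera adjusted p = 0.690). Pparg, a regulator of fat cell differentiation, rose by 1.11 ± 0.17. Lpl, which encodes lipoprotein lipase, had a log2 fold change of -0.82 ± 0.26 (adjusted p = 0.0337), a call lost without HGF 1, HGF 2, Control 1 or Control 3 (adjusted p = 0.0512 to 0.109). The 2 lymphocyte genes measured, Lck and Cd79a, had log2 fold changes of 0.11 ± 0.27 and -0.40 ± 0.66 and did not pass.

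**Figure D3:**
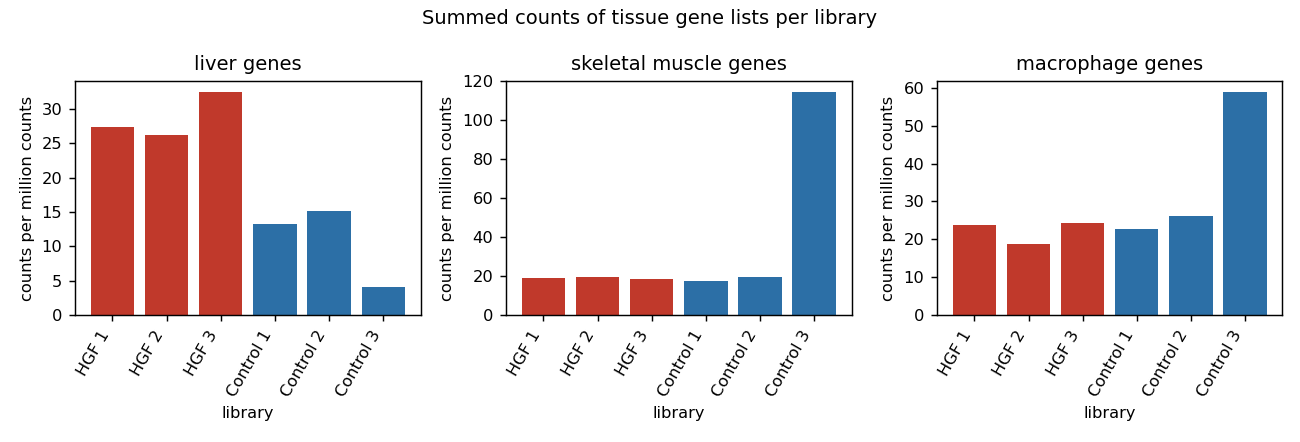
Summed counts of liver, skeletal muscle and macrophage gene lists in each of the 6 libraries, in counts scaled to library total (CPM), with a bar per library (red HGF, blue control) and axes that start at 0. The liver bars are higher in the HGF libraries (1773, 1682 and 2127 counts against 875, 994 and 231), and the muscle and macrophage bars are highest in Control 3 (6529 and 3359 counts).

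Terms of the deposited gene annotation were tested in the same way as the lists. Of 299 KEGG pathways tested, 67 passed camera at adjusted p 0.05 (62 up and 5 down), and of 1980 Gene Ontology terms 132 passed (101 up and 31 down). The pathway Ribosome had 71 genes higher and 7 lower of 130 (adjusted p = 2.60e-07, and adjusted p = 0.515 with an estimated correlation). ECM-receptor interaction had 31 higher and 10 lower of 64 (adjusted p = 2.88e-04, and adjusted p = 0.463 with an estimated correlation), and the term peptidase inhibitor activity 24 higher and 3 lower of 45 with a median of 1.09 (adjusted p = 9.05e-05, and adjusted p = 0.695 with an estimated correlation). That median was 0.0983 with limma on log2(FPKM + 1) and no filter, and 0.80 without the 6 members that are also in the liver lists (21 higher and 3 lower of 39), a test chosen after seeing the data. The median of ECM-receptor interaction was 0.36 and ranged from 0.030 to 0.43 over the fits. For Ribosome it was 0.19 and ranged from 0.034 to 0.24. Among terms that fell, the pathway for glycosylphosphatidylinositol anchors, which tether proteins to the membrane, had 1 higher and 14 lower of 24 (adjusted p = 0.00374, and adjusted p = 0.446 with an estimated correlation). The term centriole had 8 higher and 44 lower of 106 (adjusted p = 0.00177), and cilium assembly 13 higher and 51 lower of 143 (adjusted p = 0.00835), both with adjusted p = 0.695 with an estimated correlation. With an estimated correlation 0 pathways and 0 terms passed (27 and 102 at an unadjusted p under 0.05), and the 199 calls became 363 with no low-count filter and 123 with a GC correction chosen after seeing the data.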

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

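The alternatives were chosen before the data were examined, except division of counts by 4, the GC correction and the removal of tissue genes, which were chosen after seeing the data. Of 3567 values of the genes taken by the naming rule under the alternatives, 3512 kept direction and side of the threshold or made no call in either fit. Of the others, 51 missed the threshold, 3 passed it newly and 1 turned. Most of these genes were picked for a large change or a small p in these same libraries, so their stability does not carry over to the other calls. Of 875 list values, judged by camera's direction and not by the sign of the median, 847 kept both or made no call in either fit, 24 missed the threshold, 2 passed it newly and 2 turned. Atp5c1 was -0.0196 (adjusted p = 0.692) and the oxidative phosphorylation list -0.11 (adjusted p = 0.0174) with quantile-normalised FPKM, and the mitochondrial transcripts were 0.11 (adjusted p = 5.16e-04) with the GC correction. DESeq2 called 6641 genes, of which 6190 were shared and all had the same direction, edgeR without a filter 5616, median-of-ratios scaling 6630, counts divided by 4 6849, the GC correction 6944 and the fit without tissue genes 6676. The number of higher genes fell from 3316 to 2061 with limma on log2(FPKM + 1), 2050 and 2053 with pseudocounts of 0.1 and 0.5, 2065 with no filter, 1568 with a minimum FPKM of 5 (4298 genes in all, with fewer genes tested), 2041 without a variance trend and 2068 with robust variance. The share of higher calls was 32.4% to 36.5% in these and TPM fits, 52.2% with median-of-ratios scaling of FPKM and 46.7% with quantile normalisation, against 49.8%. Median-of-ratios scaling alone, with the same test, pseudocount and 11760 genes, took the higher genes from 2061 to 3084, so the library scaling of FPKM set much of this shift. The number of genes past 2-fold fell from 1000 to 133 with limma on log2(FPKM + 1), 327 and 206 with pseudocounts of 0.1 and 0.5, 129 with no filter, 92 with a minimum FPKM of 5, 155 with median-of-ratios scaling, 152 with quantile normalisation, 358 with TPM, 132 without a trend and 129 with robust variance. Within limma a smaller pseudocount and the rescaling to TPM raised this number most, and the parts of the test and the scale in the fall from 1000 were not separated. Annotation terms numbered 199, but 363 without a filter in edgeR, 369 without one in limma, 118 with a minimum FPKM of 5, 125 with median-of-ratios scaling of FPKM, 98 with quantile normalisation and 123 with the GC correction, and the cause was not tested. Lists past the threshold went from 23 to 0 with an estimated correlation. Leaving out each library in turn gave 4893 to 6228 genes, 2553 to 3174 higher, 2340 to 3054 lower, 841 to 957 past 2-fold, 23 to 24 lists and 194 to 211 terms. The replicate numbers did not pair the libraries (correlations of same-numbered deviations 0.0592, -0.03 and 0.0377), and a fit with the replicate number as a block called 6737 genes (3365 higher and 3372 lower), 864 past 2-fold, 23 lists and 222 terms. The simulations recovered 54.5% of 1.5-fold changes.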

Other observations

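The gene families, their named genes and the tests on liver, muscle and macrophage transcripts and on a further list of mitotic genes were chosen only after the result was seen. The counts over other splits of the libraries were chosen before, and the GC test of the mitotic genes was chosen after their fall and a GC trend were seen but before the corrected values were. Families were formed by gene symbol and tested with camera, adjusted over the 11 families. Keratin genes rose in 10 of 16 and fell in 0 (median log2 fold change 1.40, adjusted p = 7.73e-06, and adjusted p = 0.0946 with an estimated correlation), with Krt16, a keratin of activated epidermis, at 3.43 ± 0.21 (SE). Serpinb genes, which encode intracellular protease inhibitors, rose in 8 of 10 and fell in 1 (median 1.14, adjusted p = 5.75e-04, and adjusted p = 0.0980 with an estimated correlation). Ly6 genes, which encode small membrane-anchored proteins, rose in 5 of 8 and fell in 0 (median 2.05, adjusted p = 3.13e-05, and adjusted p = 0.0980 with an estimated correlation), with Ly6c1 at a mean FPKM of 125 against 30.7. S100a genes rose in 5 of 11 and fell in 0 (median 0.51, adjusted p = 0.00328, and adjusted p = 0.0946 with an estimated correlation), and collagen genes in 14 of 32 with 5 lower (median 0.27, adjusted p = 0.00328, and adjusted p = 0.103 with an estimated correlation). Glutathione transferase alpha genes rose in 3 of 4 and fell in 0 (adjusted p = 0.0167, and adjusted p = 0.130 with an estimated correlation), with Gsta1 at 2.97 ± 0.30 and a low mean FPKM of 1.84 against 0.239. Members of the Ly6, Gsta and Serpinb families resemble each other, and reads could be split between them.

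Class II genes of the major histocompatibility complex fell in 4 of 6 and rose in 0 (median -2.07, adjusted p = 0.00328, and adjusted p = 0.0946 with an estimated correlation), each at a low level in controls, as H2-Aa with counts of 88, 125 and 166 against 37, 11 and 11, the highest in Control 3, which also held the most of some macrophage transcripts. Zinc finger genes of the Zfp series fell in 117 of 343 and rose in 25 (median -0.26, adjusted p = 3.13e-05, and adjusted p = 0.0946 with an estimated correlation), and a GC correction left a median of -0.17 (adjusted p = 0.0413). Genes of glycosylphosphatidylinositol anchor synthesis fell in 12 of 21 and rose in 1 (median -0.29, adjusted p = 0.00328, and adjusted p = 0.102 with an estimated correlation), and a GC correction left a median of -0.19 (10 lower and 2 higher, adjusted p = 0.0115). Bardet-Biedl and intraflagellar transport genes, which serve the cilium, fell in 7 of 22 and rose in 2 (median -0.19, adjusted p = 0.00649, and adjusted p = 0.102 with an estimated correlation). Dual-specificity phosphatase genes gave 8 higher and 3 lower of 22 and did not pass (adjusted p = 0.126), with a median of 0.08 that was -0.01 with limma on log2(FPKM + 1) and no filter. The medians of the other 10 families kept their sign under every alternative that measured them, but not their size: the smallest were -0.21 for class II, 0.32 for glutathione transferase alpha, 0.39 for Serpinb, 0.07 for S100a, 0.06 for collagen, 0.55 for keratin and 0.86 for Ly6 genes. Since the families were chosen after their values in these same libraries were seen, the kept signs are no independent support.

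Liver transcripts were higher in all 3 HGF libraries, at 0.00262% to 0.00324% of counts for a further liver list against 0.000405% to 0.00152% in controls. Of 25 liver genes outside the fixed lists, 16 (64%) were at least 2-fold higher with HGF, and 13 of the 25 were at the floor or above in the controls as well. With the floor for controls, 4 of the 25 had too few counts to reach 2-fold in any case. Of the other 21, a choice made after the first share was seen, 76.2% were at least 2-fold higher, narrowly past the share set for liver RNA, which is consistent with a little of it in the HGF libraries. The relative counts of 15 liver genes varied over the HGF libraries by a chi-square per degree of freedom of 1.03, as 1 shared liver source would give, but 1510 other genes of like counts gave 1.55, so this does not separate a shared source from expression by the cells. Transcription factor genes of hepatocytes had a median log2 fold change of 0.334 (10 genes, with Foxa2 and Tbx3 higher and Onecut2 lower). The SE of this median, 0.208, comes from the spread over the 10 genes, taken as independent, and not over libraries. The median was short of a programme raised as a whole and not enough to exclude one. The transcription factor gene Hnf4a, which is in the fixed marker list and not among these 10, had 352 counts with HGF against 157 in controls (2.33-fold). A partial hepatocyte programme in cells given HGF, which would raise the same genes, therefore stays open beside liver RNA, and the labels name no sort or gate that would remove liver cells.

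Control 3 held far more of some transcripts than the other controls, such as Acta1, the skeletal muscle actin gene, with 6493 counts against 41 and 7, and Atp2a1, the muscle calcium pump gene, with 5984 against 26 and 42. Of 29 muscle genes outside the fixed lists, 22 (75.9%) were at least 3-fold above the other controls, with a median ratio of 11.9. Only 15 of the 29 were at the floor or above in the other controls, and the rest entered through their counts in Control 3. Every gene short of 3-fold was among these 15 (Ldb3, Hrc, Tnnc1, Tnni1, Tnnt1, Txlnb and Srl, ratios 0.945 to 2.67). The share over the 29 is therefore raised by how genes entered, and a small amount of skeletal muscle RNA in Control 3 stays open. Of 20 macrophage genes, 10 (50%) were at least 2-fold above them, with Adgre1, a macrophage surface gene, at 963 counts against 12 and 19, so macrophage RNA stays open, and a general carry-over of liver RNA is argued against by 1 of 11 liver genes (9.09%) at 2-fold. No biological explanation was tested, since the design sets no control apart. Without Control 3, 5921 genes passed and 5573 of them were among the 6665.

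The lower G2 and mitosis genes passed camera with its preset correlation before and after a GC trend between the groups was removed, and before the removal missed the threshold with an estimated one (adjusted p = 0.357). The median of the list was -0.17 before and -0.168 after the correction (SE of the median 0.048, camera adjusted p = 0.00288). After it 16 genes were lower and 2 higher of 30, which argues against a GC trend as the whole cause. A further list of 35 genes of the same phase, chosen after the first result was seen, had a median of -0.183 (18 lower and 1 higher, camera p = 4.06e-05, and p = 0.00941 with an estimated correlation), or -0.12 after the correction (12 lower, p = 0.0256). A hypothesis is that these transcripts fell as a class in cells given HGF. Whether fewer cells were in that phase or each held less of these transcripts is open, as cell cycle phase was not analysed here.

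The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and each other split still sets 2 HGF libraries against 1. Any difference between HGF and control then lies within both groups of such a split and widens their spread, so few gene calls were to be expected there. The gene counts of the other splits therefore do not show how many calls noise alone would give. The real split gave 6665 genes, 1000 genes past 2-fold, 23 lists and 199 terms, and the highest of the other splits gave 0, 0, 21 and 80. At an unadjusted p under 0.05 edgeR gave 8128 genes for the real split and 120 to 512 for the others. For each of the 4 results 1 of the 10 splits, the real one, gave a value as large.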
